A study of Mus musculus with 7 samples.

How the data were processed

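RNA sequencing was performed on macrophages sorted from inguinal white adipose tissue (IWAT, a subcutaneous fat depot) of ChAT-eGFP reporter mice, in which an enhanced green fluorescent protein reports activity of the Chat locus. Per the labels, the mice were housed at 4 °C for 4 h. Live CD45-positive, CD11b-positive, CD64-positive cells without Ly6G, SiglecF, NK1.1, CD3 or CD19 were separated by eGFP fluorescence and sorted into lysis buffer. Polyadenylated RNA was amplified with a kit for single cells and low input and sequenced as read pairs, per the labels' protocols. The groups were 4 ChAT-eGFP-negative and 3 ChAT-eGFP-positive libraries, assigned from the sample titles. The labels do not state that the libraries of a group came from separate animals. The p-values therefore measure only the spread between these samples, which may be technical.

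The submitters' processing notes name bcl2fastq, cutadapt 2.3, STAR 2.7.8a, RSEM 1.3.3, FastQC 0.11.8 and the mouse genome build GRCm38, without giving the order of the steps. The deposited table holds 55426 rows and 1 column per library, and the authors named it as raw counts. The deposited values are FPKM (fragments per gene, scaled to transcript length and to the total of the library), as judged from the values themselves. Low values of genes with 1 annotated transcript fell on steps inversely proportional to transcript length, and 0.64 to 1.03 percent of values were whole numbers. The steps gave an estimated depth for each library. Between 93.0 and 96.5 percent of the low values used lay within 0.15 of a whole number of fragments. The estimated depths were 296558, 1331734, 2685159 and 2406225 fragments in ChAT-eGFP-negative replicates 1 to 4. They were 350300, 184249 and 274830 fragments in ChAT-eGFP-positive replicates 1 to 3. A single fragment in a transcript of 2 kb was worth 1.89, 0.422, 0.212 and 0.231 FPKM in the negative libraries and 1.62, 3.05 and 2.04 FPKM in the positive libraries. Values of a few FPKM in the positive libraries therefore rest on very few fragments, and genes with several transcripts have no fixed step, so whole fragments were not recovered for every gene. An exact 0 in such a table can be a failed estimate, and genes used by every cell were among those at 0, so a gene is said only to be listed at 0.

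The design fixed before the data were examined assumed counts and a count model with its own scaling. FPKM are not counts, so that model was not used. The test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with group as the only term and with trended, robust variance shrinkage. Genes with at least 1 FPKM in at least 3 libraries were tested, which left 30491 genes, and 5 rows of reporter sequences were left out. Benjamini-Hochberg adjustment was made over all genes tested, with a threshold of 0.05. Log2 fold changes are ChAT-eGFP-positive minus ChAT-eGFP-negative on the log2(FPKM + 1) scale, which understates the change of low genes. The table also held 1 unlabelled number beside Chat, which the authors deposited without a heading and which reads as a p-value. It was not used as a result.

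A total of 27 gene symbols that a spreadsheet had turned into dates were restored from their gene identifiers, and 118 symbols that occur more than once were kept apart by identifier. Gene positions, biotypes and transcript lengths were taken from the GENCODE annotation of GRCm38, the build named in the processing notes. Reads shared between near-identical genes, pseudogenes and their parents, or overlapping genes cannot be told apart in this table, and strand was not used here.

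A total of 33 gene lists were written before the data were examined, and 845 of their 847 written members were matched to rows and counted once per list. Lists were tested with limma's camera, which compares the members of a list with all other genes, at a preset correlation of 0.01. The estimated correlation and the rotation test fry were run beside it, with adjustment over the 33 lists. Counts within a list are given over all genes tested and adjusted over the list alone. The marker levels of 10 other cell types were sums of FPKM. These sums, the measures of depth and quality, and the distance between group centroids in principal components were compared by two-sided exact permutation over the 35 splits of the 7 libraries, for which the smallest possible p is 0.0286.

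Named genes followed a rule written before the data were examined. It takes every measured member of the cholinergic list, the 12 highest and 12 lowest log2 fold changes among called genes with a mean of at least 50 and no overlap between groups, and up to 3 members with the smallest p of each list. The minimum of 50 was applied to FPKM. Predicted and unnamed genes were left out of the 12, and a direction with fewer than 12 was filled by smallest p among genes that did not pass. Genes named outside the rule were chosen after their values were seen. They include Csn1s1, Fabp2, Apoa5, Mrc1, Retnla, Gm10800 and the neighbours of Chat (Ercc6, Prrxl1 and Ogdhl). A set of 1503 genes for odorant, vomeronasal and taste receptors, named chemosensory receptor genes below, was chosen after the data were seen as a measure of background, because fat tissue is not known to use them as a class.

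The limma fit was tested on simulated data for this comparison with 50 genes changed at each of 4 sizes among 30491 genes. It recovered 0 percent of genes with a log2 change of 2, 12 percent at 4, 58 percent at 6 and 88 percent at 8, with 0 genes of the wrong sign and 3 unchanged genes called. Alternatives fixed beforehand were 2 other scalings, sample quality weights, no filter and a filter of 50 FPKM, variance shrinkage that is not robust, the replicate number as a block, mitochondrial and ribosomal protein genes left out, a minimum fold of 1.5, a threshold of 0.01, other list tests, mean log2 levels of marker lists, and each library left out in turn. Alternatives added after seeing the data were pseudocounts of 0.1 and 10, quantile normalization, no trend, subtraction of the mean chemosensory receptor level (with rescaling over nuclear protein-coding genes and a filter and pseudocount of 10), thinning to the lowest depth, and leaving out negative replicate 1 with positive replicate 1. Figures and permutation tests used numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.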

Results

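Transcript levels were measured in 7 libraries of macrophages sorted from the inguinal fat of cold-exposed ChAT-eGFP reporter mice. The 4 ChAT-eGFP-negative libraries held an estimated 296558 to 2685159 fragments each, and the 3 ChAT-eGFP-positive libraries 184249 to 350300. The means were 1.68e+06 ± 1.09e+06 (SD, n = 4) and 269790 ± 83140 (SD, n = 3), and the difference did not pass the exact permutation test (p = 0.0857). The comparison asks how macrophages with activity of the choline acetyltransferase reporter differ in transcript levels from those without it.

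Chat, which encodes choline acetyltransferase, the enzyme that makes acetylcholine, was listed at 63.85, 22.03 and 24.10 FPKM in the positive libraries and at 8.91, 8.45, 0.28 and 2.10 FPKM in the negative libraries. Slc18a3, which encodes the vesicular acetylcholine transporter and lies within the span of Chat, had a mean of 20.2 ± 7.79 FPKM (SD, n = 3) in the positive libraries and 2.97 ± 2.48 (SD, n = 4) in the negative libraries. The row of the eGFP sequence was listed at 0 in all 4 negative libraries and at 2.91, 5.43 and 14.52 FPKM in the positive libraries. In all 3 rows every positive library lay above every negative library, with an exact permutation p of 0.0286 on FPKM, the smallest possible. The same separation held in 8052 of the 30491 genes tested (26.4 percent), so it does not set these rows apart. On log2(FPKM + 1) the exact permutation p was 0.0286 for Chat and eGFP and 0.0571 for Slc18a3. In the fit across all genes, neither Chat (log2 fold change 2.93, SE 0.997, adjusted p = 0.101) nor Slc18a3 (2.61, SE 0.904, adjusted p = 0.103) passed the threshold. Chat (ENSMUSG00000021919) spans bases 32408203 to 32465989 of chromosome 14 in GRCm38 and has 8 annotated transcripts, and Slc18a3 (ENSMUSG00000100241) spans bases 32462438 to 32464850. The values rest on few fragments. For Chat these were an estimated 9.36, 1.78 and 2.90 in the positive and 1.16, 4.93, 0.31 and 2.32 in the negative libraries. That estimate takes the median length of the 8 transcripts, 658.5 bp, and a longer transcript would give more. For eGFP the estimates were 0.49, 0.50 and 2.0 in the positive libraries, taking its coding sequence as the length. The neighbouring genes Ercc6 (4.23 ± 2.84 FPKM in the negative and 37.0 ± 23.4 in the positive libraries) and Prrxl1 (8.73 ± 6.90 and 35.05 ± 3.52) also had every positive library above every negative one (exact permutation p = 0.0286 for each on FPKM, and on log2(FPKM + 1) 0.0286 for Ercc6 and 0.0571 for Prrxl1). Ogdhl, a gene on the other side of Chat, was listed at 6.45, 0 and 0 FPKM in the positive libraries. It was listed at 0, 0, 0 and 0.12 FPKM in the negative libraries (exact permutation p = 0.429 on FPKM). Sample quality weights moved Chat past the threshold (log2 fold change 3.34, adjusted p = 0.0235, in a range of 0.0235 to 0.371 over the alternatives), in a fit that called 8903 genes higher, among them 784 of 1352 chemosensory receptor genes.

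**Figure D1:**
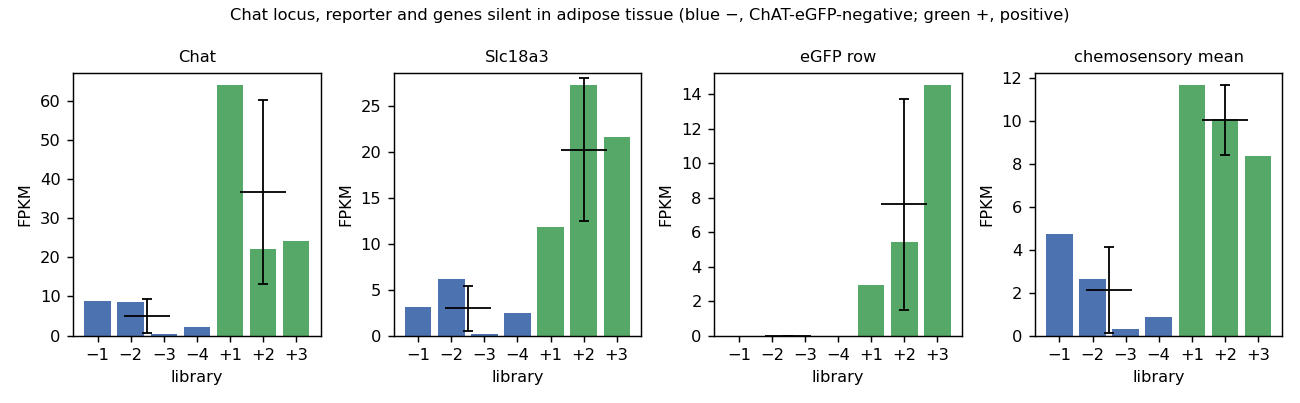
FPKM (linear axis from 0) per library for Chat, Slc18a3, the eGFP row and the mean of 1503 chemosensory receptor genes, with ChAT-eGFP-negative libraries in blue and positive libraries in green, and black marks for the mean and SD of each group. The positive libraries lie above the negative ones in all 4 panels, and the mean of chemosensory receptors runs from 8.38 to 11.7 in the positive and from 0.294 to 4.72 in the negative libraries.

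Of the 22 measured members of the list of cholinergic machinery, 0 passed the threshold over all genes, and 0 passed when adjusted over the list alone. A total of 19 had a log2 fold change above 0, and the list's median was 1.80. Among the receptors, Chrm3 was listed at 1.76 ± 1.35 FPKM in the negative and 16.1 ± 9.83 FPKM in the positive libraries (log2 fold change 2.64, adjusted p = 0.0955). Chrm4 had a log2 fold change of 2.68 (adjusted p = 0.0827). Slc5a7, the high-affinity choline transporter, was at 1.58 ± 1.596 and 7.11 ± 0.444 FPKM (log2 fold change 1.87, adjusted p = 0.137), and Ache, which breaks acetylcholine down, was at 7.22 ± 10.4 and 13.3 ± 2.10 FPKM (1.64, adjusted p = 0.270). Against all other genes the list was not called (camera adjusted p = 0.109, and adjusted p = 0.669 with an estimated correlation). The mean of chemosensory receptor genes differed in the same direction, at 2.13 ± 1.99 FPKM in the negative and 10.04 ± 1.64 FPKM in the positive libraries (exact permutation p = 0.0286, 0.0714 after adjustment over 10 measures).

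The strongest differences elsewhere were toward lower levels in ChAT-eGFP-positive macrophages, and they included immune and mitochondrial genes. Bst2, an interferon-induced membrane protein, was listed at 163, 160, 369 and 99.8 FPKM in the negative libraries and at 0 in all 3 positive libraries (adjusted p = 0.00498). Cd79b, a chain of the B cell receptor complex, was at 237, 148, 139 and 136 FPKM in the negative libraries and at 0, 0 and 3.01 in the positive libraries (adjusted p = 0.00756). Fcgr3, a low-affinity Fc receptor for IgG, fell from 326, 204, 747 and 690 FPKM in the negative libraries to 2.68, 0 and 16.9 FPKM in the positive libraries (adjusted p = 0.0168). Polr2j, which encodes a subunit of RNA polymerase II, was at 353, 189, 152 and 123 FPKM in the negative libraries and listed at 0 in the positive ones (adjusted p = 0.00469). Subunits of respiratory complex I were listed at 0 in the positive libraries too, with Ndufs2 at 67.3, 277, 77.0 and 172 FPKM in the negative ones (adjusted p = 0.00606) and Ndufb6 at 203, 62.0, 51.3 and 243 FPKM (adjusted p = 0.00756). In all, limma called 186 of 30491 genes higher and 129 lower in the positive libraries. At an unadjusted p under 0.05 there were 8117 higher and 1373 lower. The median log2 fold change of all genes was 1.26 as deposited, and it was 0.22 with median-of-ratios scaling, 0.32 with upper quartile scaling and 0.16 with quantile normalization. The split of higher against lower moved with these scalings from 186 and 129 (59.0 percent higher) to 20 and 108 (15.6 percent), 26 and 144 (15.3 percent), and 25 and 173 (12.6 percent). Among the 2573 genes left by a filter of 50 FPKM in at least 3 libraries, the median log2 fold change was −1.55. The upward shift did not hold for those genes, but the filter can be met by the negative libraries alone. The counts also depended on single libraries. They were 2612 higher and 537 lower without negative replicate 1, 21 and 58 without negative replicate 2, 23 and 85 without negative replicate 3, and 10 and 50 without negative replicate 4. They were 48 and 68 without positive replicate 1, 132 and 78 without positive replicate 2, and 319 and 242 without positive replicate 3. The calls of Bst2, Cd79b, Polr2j, Ndufs2 and Ndufb6 held in all 7 of these fits, and that of Fcgr3 ended without negative replicate 3 (adjusted p = 0.0542) or 4 (0.0503). With a pseudocount of 10, 0 genes were higher and 2 lower by limma, and without both negative replicate 1 and positive replicate 1 the counts were again 0 and 2. The calls of these 6 genes ended in both settings (adjusted p of 0.0677 to 0.0764 and 0.0797 to 0.0841), as did those of all other genes named in this text as rising or falling.

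**Figure D2:**
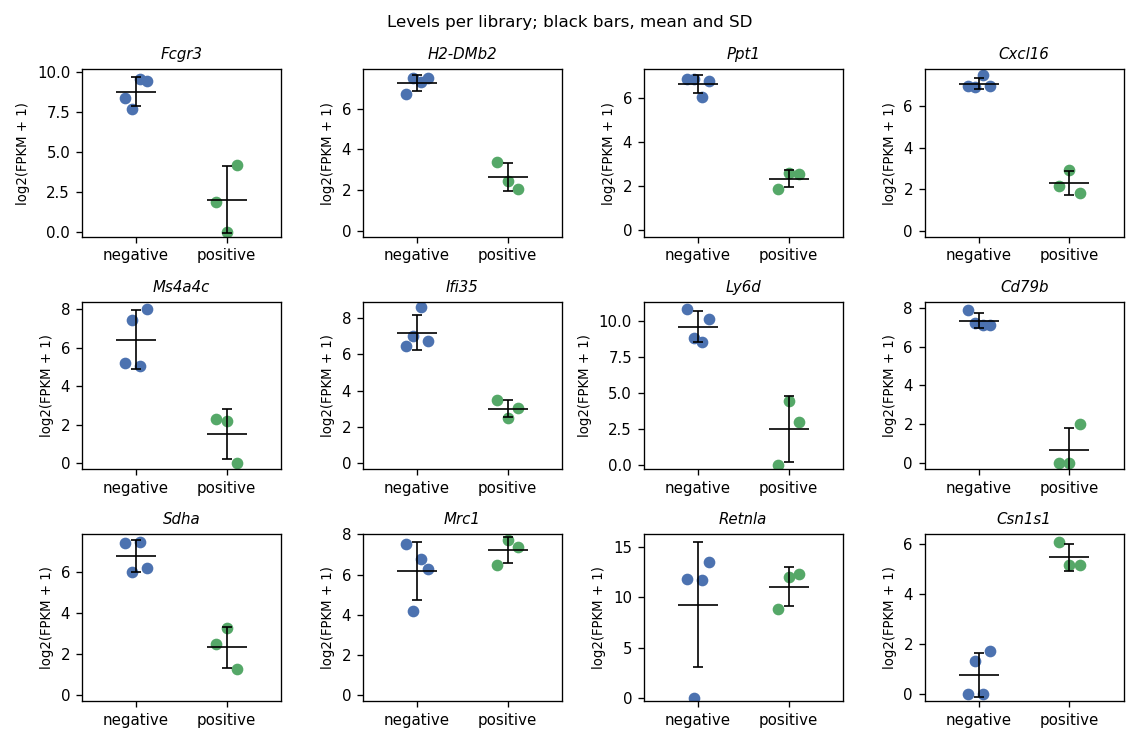
Log2(FPKM + 1) of 12 genes per library, with negative libraries in blue (n = 4), positive libraries in green (n = 3), and black bars for mean and SD. Fcgr3, H2-DMb2, Ppt1, Cxcl16, Ms4a4c, Ifi35, Ly6d, Cd79b and Sdha fell in the positive libraries and Csn1s1 rose, whereas Mrc1 and Retnla did not pass the threshold and flip in direction, Mrc1 only under 2 scalings that by construction lower all abundant genes alike and Retnla without negative replicate 2 and with sample quality weights.

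Genes that mark macrophages in general fell in the ChAT-eGFP-positive libraries relative to other genes. Of 20 measured members of the list of gated surface markers and pan-macrophage genes, 17 had a log2 fold change under 0, with a median of −2.50. Only Fcgr3 passed over all genes, and 6 members were lower when adjusted over the list alone. The list was called lower relative to other genes (camera adjusted p = 4.25e-14, and adjusted p = 0.0406 with an estimated correlation). The fry test asks whether members move one way against no change. It called none of the 21 lists that camera called lower, with a smallest adjusted p of 0.0502. A fall against no change was thus not called for these lists, which does not show that there was none. A filter of 50 FPKM, which left 2573 genes, ended 16 of the 21 calls and kept those of the pan-macrophage, MHC class II, lysosome, oxidative phosphorylation and B cell lists. The median log2 fold change of those 2573 genes was −1.55, so the genes kept were lower as a group. The filter can be met by a single group, as by Bst2 and Polr2j, which were listed at 0 in every positive library. Part of that fall may thus come from the selection. Cd14, a co-receptor for lipopolysaccharide, was at 1424 ± 1425 FPKM in the negative and 24.03 ± 21.9 FPKM in the positive libraries (log2 fold change −6.17, adjusted p = 0.0586). Ctss, a lysosomal protease of antigen processing, was at 982 ± 371 and 91.1 ± 105 FPKM (−3.95, adjusted p = 0.0639). The lysosome list fell relative to other genes, with a median of −1.88 and 30 of its 32 members under 0 (camera adjusted p = 5.30e-17, and adjusted p = 0.0406 with an estimated correlation). In it, Ppt1, a lysosomal thioesterase, fell from 100.3 ± 24.5 to 4.15 ± 1.29 FPKM (adjusted p = 0.0317), and 10 members were lower when adjusted over the list alone, against 1 over all genes. The call of Ppt1 ended without negative replicate 2 (adjusted p = 0.0592), negative replicate 4 (0.0948), positive replicate 1 (0.0832) or positive replicate 2 (0.0667). The background level of chemosensory receptor genes, 4.70 times as high in the positive libraries, moved with the same groups, here and for every list below.

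Antigen presentation genes were lower relative to other genes (fry adjusted p = 0.0502 for both MHC lists). The MHC class II list had a median log2 fold change of −2.74 over 17 members, 14 of them under 0 (camera adjusted p = 2.49e-12, and adjusted p = 0.0414 with an estimated correlation). H2-DMb2, a chain of the peptide-exchange factor H2-DM, fell from 158 ± 37.9 to 5.76 ± 3.39 FPKM (log2 fold change −4.63, SE 0.816, adjusted p = 0.0261). It was the 1 member called over all genes, against 7 adjusted over the list alone. H2-DMb1, which encodes another form of the same chain, was at 436 ± 250 and 31.8 ± 39.2 FPKM (−4.34, adjusted p = 0.0595). The call of H2-DMb2 ended without negative replicate 2 (adjusted p = 0.0559), negative replicate 4 (0.0784) or positive replicate 2 (0.0637). The MHC class I list fell relative to other genes, with a median of −2.17 and 19 of 20 members under 0 (camera adjusted p = 3.01e-12, and adjusted p = 0.0414 with an estimated correlation), although 0 members passed over all genes and 0 adjusted over the list alone. Markers of other cells that present antigen moved with the same groups, with sums of 3868 ± 2478 and 426 ± 184 FPKM for B and plasma cells and of 3759 ± 292 and 1564 ± 1619 FPKM for dendritic cells, and so did the chemosensory mean (2.13 ± 1.99 and 10.04 ± 1.64 FPKM).

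Interferon, chemokine and monocyte genes were lower relative to other genes by the preset test only. The interferon list (32 members, median −0.32) was called by camera (adjusted p = 9.17e-06) and not with an estimated correlation (adjusted p = 0.0587). Over all genes 2 members were lower, Bst2 and Ifi35, an interferon-induced protein that fell from 176 ± 140 to 7.36 ± 2.66 FPKM (adjusted p = 0.0449), and 4 were lower adjusted over the list alone. The chemokine list (22 members, median −1.51) gave a camera adjusted p = 2.78e-08, and adjusted p = 0.0552 with an estimated correlation. Its 1 called member over all genes was Cxcl16, a chemokine with a membrane-bound form, which fell from 137 ± 27.9 to 4.19 ± 2.11 FPKM (log2 fold change −4.79, adjusted p = 0.0209), and 5 were lower adjusted over the list alone. Ccl8 was at 1679 ± 1389 and 94.2 ± 68.9 FPKM (−3.88, adjusted p = 0.0796). The monocyte list (19 members, median −1.39) gave a camera adjusted p = 8.82e-08, and adjusted p = 0.127 with an estimated correlation. Ms4a4c fell from 124 ± 109 to 2.48 ± 2.15 FPKM (adjusted p = 0.0485) as its 1 called member, against 4 adjusted over the list alone, and Ly6c2 was at 721 ± 338 and 84.6 ± 112 FPKM (adjusted p = 0.0741). The call of Cxcl16 ended without negative replicate 2 (adjusted p = 0.0502), negative replicate 4 (0.0588) or positive replicate 1 (0.0541). The calls of Ifi35 and Ms4a4c ended in 6 of the 7 fits that left out 1 library, all but the fit without negative replicate 1, with adjusted p of 0.0551 to 0.104 and 0.0676 to 0.136.

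Among the lists for macrophage states, lipid-associated macrophage genes fell relative to other genes (21 members, median −1.39, camera adjusted p = 5.10e-06, and adjusted p = 0.0406 with an estimated correlation). In this list 0 members were called over all genes, and 6 were lower and 1 higher when adjusted over the list alone. Lgals3 was at 347 ± 217 and 37.7 ± 49.7 FPKM (log2 fold change −4.56, adjusted p = 0.0846), and Apoe at 8368 ± 5789 and 1095 ± 1021 FPKM (−4.20, adjusted p = 0.105). The tissue-resident list was lower by the preset test (23 members, median −0.93, camera adjusted p = 5.46e-07), which was lost with an estimated correlation (adjusted p = 0.264), and 0 members passed over all genes or adjusted over the list alone. Its member Selenop was at 935 ± 919 and 95 ± 54.2 FPKM (adjusted p = 0.115). Alternative activation was called lower relative to other genes (22 members, camera adjusted p = 0.00786), with a median of 0.15 and a mean of −0.23, and the call was lost with an estimated correlation (adjusted p = 0.0587), without negative replicate 4 (0.155), with quantile normalization (0.101) and after background subtraction (0.176). Of its members 0 passed over all genes or adjusted over the list alone. Mrc1, the mannose receptor, was listed at 183, 17.0, 108 and 76.1 FPKM in the negative and 88.5, 213 and 164 FPKM in the positive libraries, and its log2 fold change of 1.01 (adjusted p = 0.467) turned to −0.75 with median-of-ratios scaling and −0.59 with upper quartile scaling, which by construction lower every abundant gene by 1.78 and 1.61 and moved the median of all genes from 1.26 to 0.22 and 0.32. Retnla was at 3717, 0, 3384 and 11888 FPKM in the negative and 472, 4072 and 5103 FPKM in the positive libraries, and its log2 fold change of 1.78 (adjusted p = 0.629) turned to −1.31 without negative replicate 2 and −0.26 with sample quality weights.

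Inflammatory, immediate-early and complement genes fell relative to other genes. The inflammatory and NF-kB list had a median of −0.68 over 24 members (camera adjusted p = 1.62e-05, and adjusted p = 0.0406 with an estimated correlation), with 0 members called over all genes or adjusted over the list alone. Nfkbia, an inhibitor of NF-kB, was at 584 ± 407 and 38.5 ± 36.4 FPKM (adjusted p = 0.0798). The immediate-early and dissociation stress list had a median of −1.88, with 24 of 31 members under 0 (camera adjusted p = 5.31e-13, and adjusted p = 0.0414 with an estimated correlation). In it 0 members were called over all genes and 2 adjusted over the list alone. Dusp1, a phosphatase induced by stress, was at 1563 ± 1698 and 67.7 ± 84.8 FPKM (log2 fold change −5.09, adjusted p = 0.0711). The complement and scavenging list had a median of −1.07 over 26 members (camera adjusted p = 3.19e-07, and adjusted p = 0.0492 with an estimated correlation), with 0 members called over all genes and 4 adjusted over the list alone, and Cfp, or properdin, was at 255 ± 232 and 10.8 ± 8.68 FPKM (adjusted p = 0.0718).

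Nuclear-encoded genes of oxidative phosphorylation fell relative to other genes. All 38 nuclear-encoded members of the oxidative phosphorylation list had a log2 fold change under 0, with a median of −2.33 (camera adjusted p = 1.77e-22, and adjusted p = 0.0456 with an estimated correlation). Ndufs2 and Sdha passed over all genes, and 9 members adjusted over the list alone. Sdha, a subunit of succinate dehydrogenase, fell from 118 ± 59.6 to 4.76 ± 3.52 FPKM (adjusted p = 0.0394), a call that ended in 6 of the 7 fits without 1 library, all but the fit without negative replicate 1 (adjusted p of 0.0587 to 0.0929). All 35 ribosomal protein genes were also under 0, with a median of −1.74. Their camera adjusted p = 1.03e-17 was lost with an estimated correlation (adjusted p = 0.209), and 0 passed over all genes or adjusted over the list alone. Rpl3 was at 920 ± 283 and 115 ± 84.0 FPKM (log2 fold change −3.18, adjusted p = 0.0824). Glycolysis and hypoxia genes were called lower only relative to other genes, with 15 of 28 members under 0 (median −0.17, camera adjusted p = 1.08e-04, and adjusted p = 0.0406 with an estimated correlation), with 0 members called over all genes and 3 adjusted over the list alone. The call was lost after background subtraction (adjusted p = 0.139). Their member Aldoa, an aldolase, was at 343 ± 189 and 19.1 ± 10.4 FPKM (−4.12, adjusted p = 0.0507). Mitochondrially encoded genes were not called on the values as deposited (15 members, median 0.60, camera adjusted p = 0.382), and their share of all FPKM was 2.73 ± 0.516 percent in the negative and 4.29 ± 0.394 percent in the positive libraries (exact permutation p = 0.0286, 0.0714 after adjustment over 10 measures). The cholesterol list (30 members) was called lower relative to other genes (camera adjusted p = 0.0249) with a median of 0.15 and a mean of 0.20, and the call was lost with an estimated correlation (adjusted p = 0.208), without negative replicate 4 (adjusted p = 0.0646), without positive replicate 1 (0.0503), without both replicates 1 (0.0519), without a filter (0.0729), with a pseudocount of 0.1 (0.0858), with quantile normalization (0.233) and after background subtraction (0.991).

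**Figure D3:**
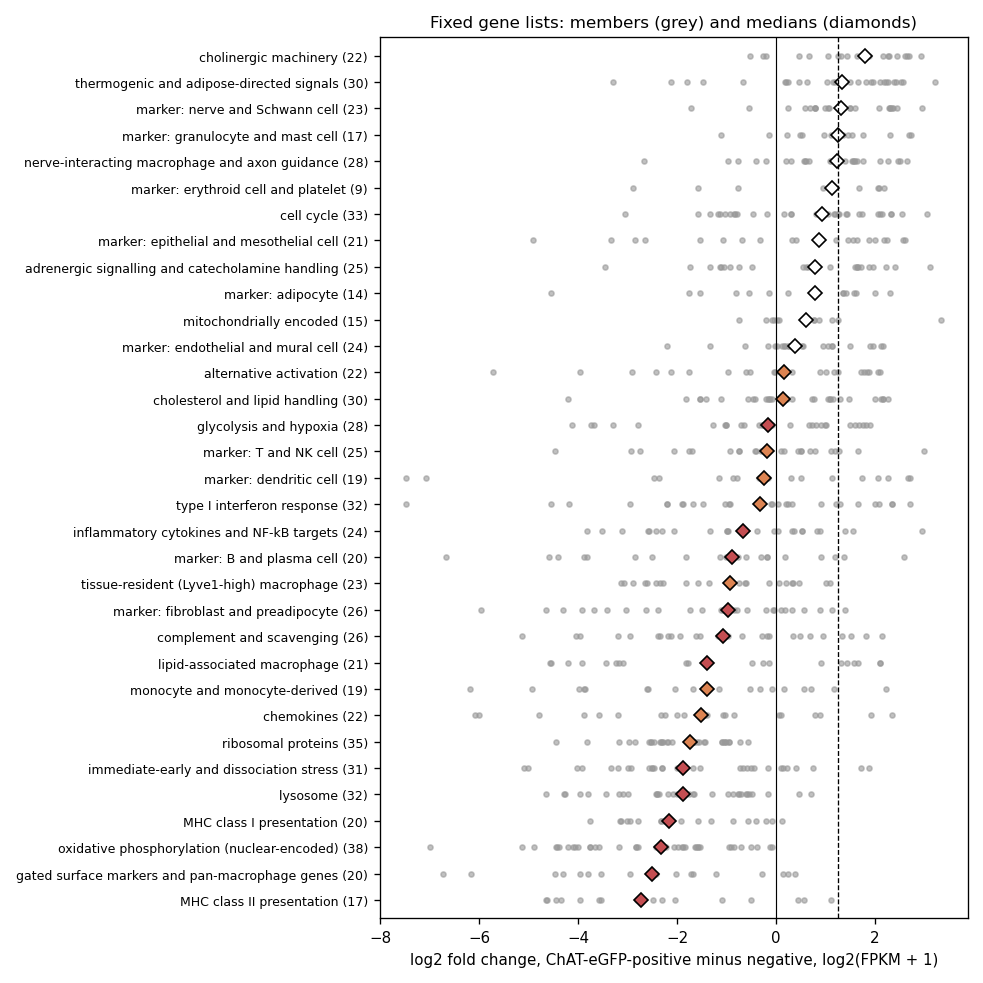
Log2 fold change (positive minus negative, log2(FPKM + 1) scale) of the members (grey points) of 33 fixed gene lists and their medians (diamonds), with the number of members tested in brackets and a dashed line at the median of all genes (1.26). Diamonds are red for the 12 lists called lower with both the preset and an estimated correlation, orange for those called with the preset correlation only, and white for the rest, and the oxidative phosphorylation and ribosomal protein members all lie under 0.

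Markers of cell types that the gate was set to exclude were also measured. The sum of B and plasma cell markers was 3868 ± 2478 FPKM in the negative and 426 ± 184 FPKM in the positive libraries (exact permutation p = 0.0571, 0.286 after adjustment over 10 lists), although CD19-positive cells were gated out. Ighm, the heavy chain of IgM, fell from 417 ± 228 to 18.3 ± 9.69 FPKM (adjusted p = 0.0368), and Cd79b fell as given above. The B cell list was called lower relative to other genes (20 members, median −0.90, camera adjusted p = 7.47e-08, and adjusted p = 0.0456 with an estimated correlation), with 2 members called over all genes and 5 adjusted over the list alone. The call of Ighm ended without negative replicate 2 (adjusted p = 0.0609), 3 (0.0930) or 4 (0.0975), or without positive replicate 2 (0.0802). The fibroblast and preadipocyte list fell relative to other genes too (26 members, median −0.97, camera adjusted p = 1.99e-09, and adjusted p = 0.0414 with an estimated correlation). In it 0 members passed over all genes and 8 adjusted over the list alone. The matrix proteoglycans Dcn (681 ± 528 and 62.9 ± 38.7 FPKM, adjusted p = 0.0813) and Lum (113 ± 103 and 6.59 ± 4.44 FPKM, adjusted p = 0.0639) did not pass. The dendritic cell list was lower by the preset test (19 members, median −0.25, camera adjusted p = 0.00340), which was lost with an estimated correlation (adjusted p = 0.209) and without positive replicate 1 (adjusted p = 0.135). Bst2 and Ly6d were its 2 members called lower over all genes, and adjusted over the list alone 2 were lower and 2 higher. Ly6d fell from 921 ± 652 FPKM to 0, 20.8 and 6.94 FPKM in the 3 positive libraries (adjusted p = 0.0169), a call that ended without negative replicate 2 (0.0502) or 4 (0.0528). The sum of dendritic cell markers was 3759 ± 292 and 1564 ± 1619 FPKM (exact permutation p = 0.0286, 0.286 after adjustment). The T and NK cell list gave a camera adjusted p = 0.00220 with a median of −0.18, lost with an estimated correlation (adjusted p = 0.208), without positive replicate 1 (0.0541) and after background subtraction (0.139), and 0 of its 25 members passed over all genes or adjusted over the list alone. None of the 10 sums of marker FPKM passed adjustment (smallest adjusted p = 0.286, exact permutation).

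No list was called higher by camera on the values as deposited. The mitochondrially encoded list was called higher relative to other genes with quantile normalization (adjusted p = 0.000317), after background subtraction (0.0220) and with the filter of 50 FPKM (0.00469). It was called in 5 of 23 alternatives, and its calls beside these 3 were lower. Its median shift from all genes ran from −1.39 to 2.15. Lists of thermogenic signals (30 members, median 1.33, camera adjusted p = 0.843), nerve-interacting macrophages and axon guidance (28, median 1.24, 0.928), cell cycle (33, median 0.92, 0.157) and adrenergic signalling (25, median 0.80, 0.293) were not called. In these lists 0 members were called over all genes, and adjusted over the list alone there were 0 calls except 1 higher and 1 lower member of the adrenergic list. The fry test, which asks only whether members move one way, called the thermogenic list higher (adjusted p = 0.0340). Its member Vegfb, a vascular growth factor, was at 6.34 ± 5.66 and 53.6 ± 30.2 FPKM (log2 fold change 3.21, adjusted p = 0.0980), and Nrg1, the growth factor neuregulin, at 8.86 ± 6.33 and 47.8 ± 16.0 FPKM (2.53, adjusted p = 0.108). Slit2, an axon guidance ligand, was at 7.10 ± 5.63 and 35.1 ± 6.84 FPKM (2.46, adjusted p = 0.115). Marker lists of granulocytes and mast cells (median 1.24, camera adjusted p = 0.607), adipocytes (0.79, 0.281), endothelial and mural cells (0.38, 0.227), nerve and Schwann cells (1.32, 0.292), epithelial and mesothelial cells (0.86, 0.319), and erythroid cells and platelets (1.12, 0.925) were not called either, with 0 members called over all genes or adjusted over the list alone. The endothelial list was called lower by camera in 4 of 23 alternatives (smallest adjusted p = 0.00494), among them those without negative replicate 2 (0.0445) or 3 (0.0365). The cell cycle list was called lower by camera in 3 of 24 alternatives (smallest adjusted p = 0.0296), among them those without negative replicate 3 (0.0434) or positive replicate 3 (0.0440).

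Of the 186 genes called higher 42 were protein coding (22.6 percent), and of the 129 called lower 67 (51.9 percent), against 60.0 percent of all genes tested. Processed pseudogenes numbered 66 among the higher and 51 among the lower genes, lincRNAs 29 and 4, unclassified transcripts 15 and 0, and antisense genes 14 and 2. Of the higher genes 71 were listed at 0 in all 4 negative libraries, and of the lower genes 76 were listed at 0 in all 3 positive libraries. The differences between these makeups were not tested. The protein-coding genes called higher included Csn1s1, a milk casein, which rose from 0.930 ± 1.12 to 45.8 ± 19.2 FPKM (adjusted p = 0.0299). They also included Fabp2, the intestinal fatty acid-binding protein, listed at 0 in all 4 negative libraries and at 7.79, 14.6 and 9.78 FPKM in the positive libraries (adjusted p = 0.0399), and Apoa5, a liver apolipoprotein, at 0, 0, 0 and 0.590 FPKM in the negative and 6.89, 21.2 and 14.3 FPKM in the positive libraries (adjusted p = 0.0423). These 3 genes were chosen after their values were seen. Their calls ended on leaving out 1 library, for Csn1s1 in all fits but those without negative replicate 1 or positive replicate 3 (adjusted p of 0.0567 to 0.0830), and for Fabp2 (0.0521 to 0.122) and Apoa5 (0.0554 to 0.108) in all but that without negative replicate 1. The values of Fabp2 in the positive libraries stand in the same proportion as the value of a single fragment there (1.62, 3.05 and 2.04 FPKM in a transcript of 2 kb). Each may thus rest on the same small number of fragments, and their spread need not be that of its levels. No gene with a mean of at least 50 FPKM and a regular symbol was called higher. The smallest p among them belonged to Vmn1r229, a vomeronasal receptor (9.84 ± 7.58 and 132 ± 45.8 FPKM, adjusted p = 0.0547), and to Plekhm2 (13.8 ± 10.6 and 203 ± 118 FPKM, adjusted p = 0.0627) and Adcy6 (12.0 ± 8.58 and 122 ± 70.5 FPKM, adjusted p = 0.0739). Of 1352 chemosensory receptor genes tested, 8 were called higher and 0 lower, 1319 had a log2 fold change above 0, and their median was 1.87. Every positive library lay above every negative library in 8052 genes (26.4 percent), and the reverse held in 871 (2.86 percent), where chance gives 2.86 percent for each direction.

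Correlations between libraries had their lowest mean across the groups. Spearman correlations across genes had a mean of 0.497 between negative libraries (0.385 to 0.624), 0.401 between positive libraries (0.392 to 0.408) and 0.332 across the groups (0.215 to 0.463). Genes are not independent replicates, so these values only describe the libraries. The first principal component of the 1000 most variable genes held 42.7 percent of the variance and the second 17.9 percent. The distance between group centroids reached the smallest p of the exact permutation test (0.0286).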

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

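The tests of explanations and of other splits in this part were all chosen only after the results were seen, as were the chemosensory receptor genes and the near-silent genes of negative replicate 3 that several of them use.

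Single negative libraries stood far from the other 3 in 10 of the 80 values tested (12.5 percent, where chance gives about 5 percent). For 3 of the 80 at least 3 libraries were listed at 0, so that any other value stands apart, and of the other 77 values 8 (10.4 percent) did so. Groups of 3 were not tested. The sum of fibroblast and preadipocyte markers was 9505 FPKM in negative replicate 3, against 1729 to 2246 in the others. The sum of erythroid and platelet markers was 21888 FPKM in negative replicate 2, against 1133 to 4380. Retnla was listed at 0 in negative replicate 2, against 3384 to 11888 FPKM. Chrm4 was at 1.84 FPKM in negative replicate 2 and listed at 0 in the others. In negative replicate 3, Cxcl16 was at 179 FPKM (the others at 123 to 124), Ppt1 at 63.8 FPKM (108 to 116) and Ldlr at 3.24 FPKM (10.8 to 13.5). Cd79b was at 237 FPKM in negative replicate 1, against 136 to 148. In negative replicate 4, Adipoq was at 1.53 FPKM (3.13 to 3.54) and Apoa5 at 0.590 FPKM, where the others were listed at 0. The row of the eYFP sequence, which is not among the results above, was at 2.91 FPKM in positive replicate 1 and 5.43 FPKM in positive replicate 2, and listed at 0 in positive replicate 3 and every negative library (exact permutation p = 0.143). The eGFP row had the same values in positive replicates 1 and 2, and 14.52 FPKM in positive replicate 3. Taking the same length for both rows, each held an estimated 0.49 and 0.50 fragments in positive replicates 1 and 2. The eGFP and eYFP sequences thus cannot be told apart in those libraries.

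Many genes, among them genes that macrophages are not known to use, had higher FPKM in the ChAT-eGFP-positive libraries. RNA from genes active in these or other cells of the fat pad, spliced or not, is argued against only for the chemosensory receptor genes, whose median log2 fold change was 1.87 over 1352 genes (interquartile range 1.37 to 2.34). These receptors were chosen after the data were seen, as a measure of background, so they cannot decide it for other genes. The sampling of fewer fragments is argued against as well. Thinning every library to the lowest depth gave 1293 genes higher, not fewer than the 186 at full depth. The median log2 fold change of all genes tested was then 1.43, against 1.26. Thinning cannot test a cause that goes with low depth. The chemosensory mean was 4.72, 2.65, 0.294 and 0.878 FPKM in negative replicates 1 to 4. Within the negative libraries it was thus higher the lower the estimated depth, and such a cause stays open. A background spread over the genome, such as DNA carried into the libraries, stays open but was not fully even: other near-silent genes with 1 transcript had a median of 3.26 FPKM over the positives against 5.39 for chemosensory receptors, a ratio of 0.604 that lay between the bounds of the test. A biological difference between the sorted cells was tested here only through the listed genes and stays open for the rest.

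Chat and Slc18a3 were higher in the positive libraries, in the direction the sort would give. The fold changes lay within those of genes that an even background could raise: Chat was at percentile 91.7 among 627 genes of like structure at 0.5 FPKM or less in negative replicate 3 (median 1.71, 5th to 95th percentile −0.261 to 3.14), and Slc18a3 at percentile 86.3 among chemosensory receptor genes. The mean level of Chat in the positives was higher, at percentile 95.9 among the same 627 genes and 97.4 among chemosensory receptors, and that of Slc18a3 was at percentile 91.4 among the latter, so an even background is left open for Chat. Extra copies of the Chat locus in background DNA of the reporter mice cannot be told apart from transcripts, since Chat relative to the chemosensory mean differed by 0.76 on the log2 scale between groups (exact permutation p = 0.257) and rests on few fragments. Transcription of Chat in the sorted cells stays open.

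Macrophage genes fell in the positive libraries relative to other genes. The sampling of fewer fragments is argued against, since pan-macrophage genes lay −3.88 from the median of all genes after thinning to the lowest depth (adjusted p = 3.25e-13, limma camera), against −3.76 at full depth. Thinning cannot test a cause that goes with low depth. Dilution by the background cannot be told apart from a lower RNA content of these genes. After the chemosensory level was subtracted, with rescaling and a pseudocount of 10 in place of 1, pan-macrophage genes lay −2.20 from the median of all genes (adjusted p = 2.51e-05, limma camera), but 5 chemosensory receptor genes were still called higher, so background remained after the subtraction. A lower macrophage identity of the sorted cells is open too, because pan-macrophage genes (17) differed from ribosomal protein and oxidative phosphorylation genes (71) by −0.93 on the log2 scale (exact permutation p = 0.257) among members of at least 50 in the mean of the negatives, by −1.11 (p = 0.200) with that minimum on the mean of all libraries, and by −0.47 (p = 0.400) with none.

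Of the 35 splits of the 7 libraries into groups of 4 and 3, only 1, the real one, gave as many as 186 genes higher, and the highest of the others gave 85. Likewise only 1 gave as many as 129 lower, and the highest other gave 75. With 35 splits, 1 is the smallest share possible, so the real split stood above the others but chance is not excluded. Only the fit as reported was split in this way.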

How the results depend on the processing

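The alternatives with pseudocounts of 0.1 and 10, quantile normalization, no trend, background subtraction, thinning, and both replicates 1 left out were chosen after seeing the data. The count model that had been planned as an alternative and unrounded counts were not run, because the values are FPKM. Over all alternatives, log2 fold changes of single genes kept their direction and side of the threshold in 2614 cases, moved past it in 185, lost the call in 154 and turned direction in 27. Most of these genes had no call as reported, so the kept cases are largely genes that stayed uncalled. The kept cases do not measure how well calls held. Lists kept both in 675 cases, gained a call in 10, lost it in 56 and turned direction in 39, and the 10 sums of markers passed in neither form. The count of genes higher, 186 as reported, moved to 20 with median-of-ratios scaling, 26 with upper quartile scaling, 25 with quantile normalization, 69 without a filter, 10 with a pseudocount of 0.1 and 65 with background subtraction, rescaling, and a filter and pseudocount of 10 set together (111 lower, 10384 genes tested), whose effects were not separated. With thinning, which lowers the depth of 6 libraries, it was 1293. The counts higher and lower were 8903 and 1377 with sample quality weights, under which Chat also passed (3.34), and negative replicate 4 had a weight of 3.71 and negative replicate 1 of 0.401. They were 0 and 79 with a filter of 50 FPKM (146 and 650 at an unadjusted p under 0.05, limma), where only 2573 genes were tested, 30 and 76 with a minimum fold of 1.5, 4 and 22 at a threshold of 0.01, 0 and 2 with a pseudocount of 10, and 0 and 2 without both replicates 1. Leaving out each library in turn gave 10 to 2612 genes higher and 50 to 537 lower, log2 fold changes of Chat of 2.34 to 3.32, and 18 to 23 lists lower. Calls of genes named in the report also ended for Ms4a4c, Ifi35, Sdha, Ighm, Csn1s1, Fabp2 and Apoa5 with median-of-ratios scaling, for these without Ms4a4c and Sdha with upper quartile scaling, and for Ighm, Csn1s1, Fabp2 and Apoa5 with quantile normalization. They ended for Ms4a4c, Ifi35, Sdha, Fabp2 and Apoa5 without a filter, for these 5, Ly6d and Csn1s1 with a pseudocount of 0.1, and for Apoa5 without a trend. The lists called lower went from 21 to 12 with an estimated correlation, 0 with fry, which does not compare a list with other genes, and 5 with the filter of 50 FPKM. A single list was higher (1, against 0) with fry, the filter of 50 FPKM, quantile normalization and the setting with background subtraction. The direction turned for 11 of 142 genes, in 27 cases with no call in either fit, and for lists in 39 cases by the direction of the list's test, which can differ in sign from its median shift from all genes. Log2 fold changes turned with median-of-ratios scaling for Chrm1 (−0.56), Mrc1 (−0.75), Slc44a3 (−0.48), mt-Co2 (−0.66) and mt-Nd6 (−0.52), and with upper quartile scaling for the same 5 (−0.46, −0.59, −0.39, −0.49 and −0.36 in this order). By construction these scalings lower every abundant gene by 1.78 and 1.61, and the median of all genes fell from 1.26 to 0.22 and 0.32. With quantile normalization (median 0.16) they turned for Chrm1 (−1.03), Chrnb2 (−0.48), Slc44a3 (−0.70) and the row named Slc44a4 (−0.30). That row lies at bases 153973436 to 154271722 of chromosome 3, the place of Slc44a5, so its name is in doubt. Log2 fold changes also turned with sample quality weights for Retnla (−0.26), with background subtraction for Slc44a2 (0.093), and without both replicates 1 for Slc44a1 (0.19). Leaving out each library gave ranges of −1.63 to 0.36 for Chkb, −1.31 to 3.20 for Retnla, −0.58 to 0.26 for Slc44a1, −0.88 to 0.34 for Slc44a2 and −0.23 to 1.63 for Slc44a3. Of the lists, mitochondrially encoded genes turned upward and were called with quantile normalization (median shift 1.32), background subtraction (1.20) and the filter of 50 FPKM (2.15). Their other calls, of 5 in 23 alternatives, were lower. The other turned lists were not called. With that filter they were tissue-resident macrophages (−0.15), alternative activation (0.49), cholesterol and lipid handling (0.78) and cell cycle (0.75). Nerve-interacting macrophages turned with median-of-ratios scaling (−0.10), upper quartile scaling (−0.14), quantile normalization (−0.27), a pseudocount of 10 (−0.035), thinning (−0.27) and without both replicates 1 (−0.13). Thermogenic signals turned with a pseudocount of 10 (0.056), erythroid markers with a pseudocount of 0.1 (1.04), epithelial markers with background subtraction (0.74) and without both replicates 1 (0.29), and endothelial markers with background subtraction (0.084). With fry, which tests against 0, the median shifts are unchanged and only the direction of its test was upward, without a call, for alternative activation (−1.10, adjusted p = 0.911), cholesterol (−1.11, adjusted p = 0.490), adrenergic signalling (−0.46), cell cycle (−0.34), mitochondrially encoded genes (−0.66), and markers of adipocytes (−0.47), endothelial (−0.88), epithelial (−0.39) and erythroid cells (−0.14). Leaving out each library gave ranges of −0.076 to 0.23 for thermogenic signals, −0.16 to 0.15 for nerve-interacting macrophages, −0.93 to −0.32 for mitochondrially encoded genes, and −0.37 to 0.23 for granulocyte, −1.20 to −0.017 for endothelial, −0.89 to 0.24 for epithelial and −0.20 to 0.13 for erythroid markers. Except where construction is named, the cause was not tested.

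Replicate numbers 1 to 3 occur in both groups, and the labels do not say whether they mark pairs. The correlations of deviations between same-numbered libraries were 0.123, −0.00806 and 0.0467, and only positive replicate 1 correlated best with its own number. These few values cannot show whether the samples were paired. With the number as a block, 0 genes were higher and 2 lower (5429 and 1114 at an unadjusted p under 0.05, limma), in a fit with fewer residual degrees of freedom. The block also turned the direction, without a call, of Slc44a2 (0.034), Slc44a3 (−0.011) and the endothelial list (median shift −0.009). It ended the calls of all genes named as rising or falling (for the 6 first named, adjusted p of 0.0553 to 0.0784) and of the cholesterol list (adjusted p = 0.0633). At these spreads the simulated fit recovered 0 percent of genes at a log2 change of 2 and 12 percent at 4, so smaller changes were rarely detectable.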

Other observations

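The test of resident against pan-macrophage genes, in each of its forms, was chosen only after the results were seen.

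Some genes of other pathways had higher mean levels in the positive libraries, and none of the 7 given here passed the threshold. Their log2 fold changes of 1.99 to 3.21 stand in a general upward shift, with a median of 1.26 over all genes and of 1.87 over chemosensory receptor genes, whose 95th percentile of 3.03 only Nnt exceeded. Ldlr, the LDL receptor, was at 10.05 ± 4.67 FPKM (SD, n = 4) in the negative and 39.5 ± 9.78 FPKM (SD, n = 3) in the positive libraries (log2 fold change 1.99, adjusted p = 0.143, limma). Sqle, an enzyme of cholesterol synthesis, was at 7.95 ± 7.26 and 32.3 ± 14.5 FPKM (2.17, adjusted p = 0.144). Pcyt1a, an enzyme of phosphatidylcholine synthesis, was at 6.79 ± 6.54 and 25.7 ± 3.86 FPKM (2.29, adjusted p = 0.147). Adipoq, the adipocyte hormone adiponectin, was at 2.92 ± 0.946 and 19.2 ± 9.74 FPKM (2.299, adjusted p = 0.11), and S100b, a Schwann cell marker, at 0.745 ± 1.29 and 13.5 ± 9.56 FPKM (2.94, adjusted p = 0.0852). Nnt, a mitochondrial transhydrogenase, was at 18.02 ± 17.8 and 103 ± 16.4 FPKM (3.21, adjusted p = 0.0987). Olfr114, an odorant receptor, was at 12.8 ± 10.6 and 109 ± 105 FPKM (3.01, adjusted p = 0.103).

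The libraries also differed in rows that are not macrophage genes. Gm10800, at bases 98666547 to 98667301 of chromosome 2 (GRCm38), held 1.56, 0.431, 0.0417 and 0.203 percent of all FPKM in the negative libraries and 9.86, 4.86 and 2.20 percent in the positive libraries (exact permutation p = 0.0286, 0.0714 after adjustment over 10 measures). The sum of epithelial and mesothelial markers was 3655 FPKM in negative replicate 1, against 27.4 to 1300 in the other negative libraries and 302 to 507 in the positive libraries (exact permutation p = 0.571). Negative replicate 1 also lay apart on the second principal component, at −88.1, where the other 6 libraries ran from −12.5 to 45.5.

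A hypothesis from the list values is that ChAT-eGFP-positive cells may hold more macrophages of the resident type, since resident and alternative-activation genes shifted less than pan-macrophage genes. After background subtraction, rescaling and a pseudocount of 10, members with a mean of at least 50 in the negative libraries were compared. The median log2 level of 25 resident and alternative-activation genes relative to 17 pan-macrophage genes was higher by 1.39 in the positive libraries (exact permutation p = 0.0857). With the minimum on the mean of all libraries the difference was 1.77 (23 and 15 genes, exact permutation p = 0.0571), and with no minimum it was 1.22 (45 and 20 genes, exact permutation p = 0.0286, the smallest possible). These forms use the same libraries and lists that prompted the hypothesis, so they cannot support it. The p also depends on which members are kept, and background remained after the subtraction, so the hypothesis stays undecided and no independent test of it was made.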
